A study of Homo sapiens with 4 samples.

How the data were processed

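RNA abundance was measured on 4 Affymetrix Human Gene 2.0 ST arrays, which read probe sets against most human transcripts. The RNA came from SH-SY5Y cells, an adherent human neuroblastoma line of sympathetic lineage. Per the labels' protocols, 2 cultures received origamicin at 30 µM for 24 h and 2 received the solvent methanol for the same time (mock). Total RNA was purified on columns, and biotinylated cDNA was made from it for hybridisation, per the labels' protocols. The labels call the arrays of a group biological replicates without saying whether they came from separate passages or days, so p-values measure the spread between these arrays.

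The values are log2 expression per probe set as the authors deposited them. RMA (background correction, quantile normalization and probe summary) and limma are named in the submitters' processing notes, without versions. The genome build and the annotation that the authors used are not given in the sources used here. The deposited log2 values ran from 0.574 to 14.5, with array medians between 4.37 and 4.42, so they were taken as already normalized and were not normalized again. Intensities on arrays have no counting depth. The number of arrays limits the precision, and very bright probe sets can understate a change.

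The table held 53617 probe sets. A platform annotation named exactly 1 gene for 16098 of them and several genes for none, and the other 37519 are unnamed here. All gene identifiers matched the current RefSeq gene table, which changed no symbol. The named probe sets covered 14884 genes. Of the 779 genes with more than 1 named probe set, the probe set with the highest mean over the 4 arrays was kept. Genes whose mean lay below the 40th percentile of all probe sets (3.82 on the log2 scale) were left out as dim, which left 11883 genes and removed 3001. P4HB, PDIA3, PDIA4, PDIA6 and HSPA5 have no named probe set here and were not analysed. The same is true of every member of the histone, proteasome and mitochondrially encoded mRNA lists.

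Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a single prior variance, origamicin minus mock, two-sided), with all 4 arrays and no covariate. Adjusted p-values are Benjamini-Hochberg values over the 11883 genes, and the threshold was 0.05. Each log2 change is given with its moderated standard error (SE) from this fit, over 2 arrays per group unless stated. The SE of a gene list's mean is instead unmoderated, taken between the list means of the arrays. It rests on 2 arrays per group, is itself imprecise and leaves out the spread among genes. Gene lists were tested with camera, which asks whether the genes of a list rank higher or lower than the other genes, at a preset inter-gene correlation of 0.01. Of 33 lists of pathway genes and cell type markers, the 28 with at least 5 tested genes were tested, and their p-values were adjusted over those 28. Camera was repeated with an estimated correlation, and fry, which tests whether a list's genes move on balance one way, was run beside it. Counts "adjusted over the list alone" apply the Benjamini-Hochberg adjustment within 1 list. The lists, the design, the alternatives below and the rule for named genes were fixed before the data were examined.

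The rule named the 12 genes with the largest change on each side among protein-coding genes past the threshold, or, where fewer passed, those with the smallest p on that side. It also named P4HB, PDIA3, PDIA4, PDIA6, HSPA5, DDIT3, ATF4 and XBP1, the 4 members with the smallest p in the direction of each list past the threshold, and the 2 with the smallest p of other lists described.

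The alternatives were a replicate block, no filter, a filter at the 60th percentile, equal array medians, quantile normalization, the mean of a gene's probe sets, eBayes with an intensity trend, robust eBayes, leaving out each array in turn, 2 other thresholds, and all probe sets in place of genes. For lists under robust eBayes, camera was run on the moderated statistics. Cyclic loess was added after seeing the data.

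The fits were tested on simulated data, 20 draws over the 11883 genes with the means of these arrays and a spread drawn from their intensity trend, which favours the fit with that trend. The chosen fit recovered 6.4% of the genes changed by 0.5 on the log2 scale, 74.0% of those changed by 1 and 96.8% of those changed by 2. The fit with an intensity trend recovered 44.2%, 85.3% and 99.6%. Unchanged genes called per draw averaged 4.45 in the chosen fit and 9.2 with an intensity trend. Lists of 14 and 9 genes shifted by 0.3 were called in 20 of 20 draws by camera with the preset correlation and in 0 of 20 with an estimated correlation. The simulated genes were independent of one another.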

Results

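The series compared the transcriptome of SH-SY5Y neuroblastoma cells after 24 h with origamicin, described by the submitters as an inhibitor of protein disulfide isomerase (PDI), at 30 µM, with that of cells given methanol, the solvent. PDI enzymes form and rearrange disulfide bonds in proteins folding in the endoplasmic reticulum (ER). There were 2 arrays per group. Over the 11883 genes tested, the arrays of a group correlated at r = 0.995 (mock) and 0.994 (origamicin), and arrays of different groups at 0.991 to 0.992. The median absolute log2 difference was 0.09 and 0.10 within groups and 0.12 to 0.14 between groups. The first principal component, with 50.5% of the variance, separated the groups. No pair of arrays was a duplicate: at most 32 genes had identical values on 2 arrays.

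The first question was which genes differed after origamicin. Changes among the genes tested were moderate in size: 15 genes differed by at least 1 on the log2 scale, 9 higher and 6 lower. In the limma fit no gene passed an adjusted p of 0.05, and 53 genes (32 higher, 21 lower) had an adjusted p under 0.1. The 53 became 0 with a replicate block, with no filter on dim genes and with robust eBayes. At an unadjusted p under 0.05 there were 1950 genes (949 higher, 1001 lower), where chance gives 594. Without mock replicate 1 or 2 there were 1270 and 1261. The groups did not overlap for 5772 genes, 48.6% of those tested, where chance gives 33.3%. The call depended on how the spread was modelled. With an intensity trend in eBayes, 511 genes passed (254 higher, 257 lower), and 52 of the 53 genes above were among them. With the stricter 60th percentile filter, 92 genes passed, of which 91 were shared with the trend fit.

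The genes with the strongest evidence on the higher side included stress, matrix and signalling genes. ANKRD1, a transcriptional cofactor known as a target of YAP signalling, was 3.54-fold higher (log2 change 1.83 ± 0.12 SE). GDF15, a stress-induced cytokine, was 3.02-fold higher (1.59 ± 0.11), and TFPI2, a secreted serine protease inhibitor, was 2.88-fold higher (1.52 ± 0.09). EGR1, an immediate early transcription factor, was 2.11-fold higher (1.08 ± 0.10), and its other, dimmer named probe set stood at 0.65. The nuclear receptor RORB (0.96 ± 0.07), the matrix Gla protein MGP (0.91 ± 0.07), the kinase SGK1 (0.89 ± 0.07), TMEM229A (0.83 ± 0.07), the AP-1 subunit FOSL1 (0.76 ± 0.07), thioredoxin reductase TXNRD1 (0.74 ± 0.06), LHFPL6 (0.74 ± 0.06) and the kinesin KIF1C (0.72 ± 0.06) completed the 12. All 12 had an adjusted p of 0.095 in the chosen limma fit, short of the threshold, and all 12 passed in the fit with an intensity trend (adjusted p from 0.00064 to 0.023). MGP, SGK1 and ANKRD1 were dim in mock cells, at 3.92, 4.22 and 4.25 on the log2 scale, near the filter at 3.82, so their folds rest on a mock level that array background can raise.

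On the lower side, the proneural transcription factor NEUROG2 was 2.76-fold lower (log2 change -1.47 ± 0.10 SE) and the zinc finger gene INSM2 2.08-fold lower (-1.06 ± 0.08). DDIT4, an inhibitor of mTORC1 signalling, was 2.38-fold lower (-1.25 ± 0.09), and the oncogenic transcription factor MYC was 1.96-fold lower (-0.97 ± 0.08). The growth factors FGF7 (-0.91 ± 0.07) and HGF (-0.88 ± 0.07) were lower, as were the selenoprotein SELENOH (-0.86 ± 0.07), the ubiquitin ligase PDZRN3 (-0.83 ± 0.08), the clock output gene DBP (-0.75 ± 0.07), the receptor tyrosine kinase KIT (-0.70 ± 0.06), GLT8D2 (-0.69 ± 0.07) and EPAS1, which encodes HIF-2α (-0.69 ± 0.07). These 12 also had an adjusted p of 0.095 in the chosen limma fit, and 11 of them passed with an intensity trend. The exception was GLT8D2 (adjusted p = 0.053), which was dim at 4.48 in mock and 3.79 in treated cells. FGF7 was dim as well, at 4.78 and 3.86. The treated levels lie at the filter of 3.82, so the size of both changes is uncertain. The FGF7 sequence is shared with pseudogene copies. The copy FGF7P6, chosen after its values were seen, stood at -0.67 ± 0.08, and the value of FGF7 is uncertain to the extent that their probes share targets.

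**Figure D1:**
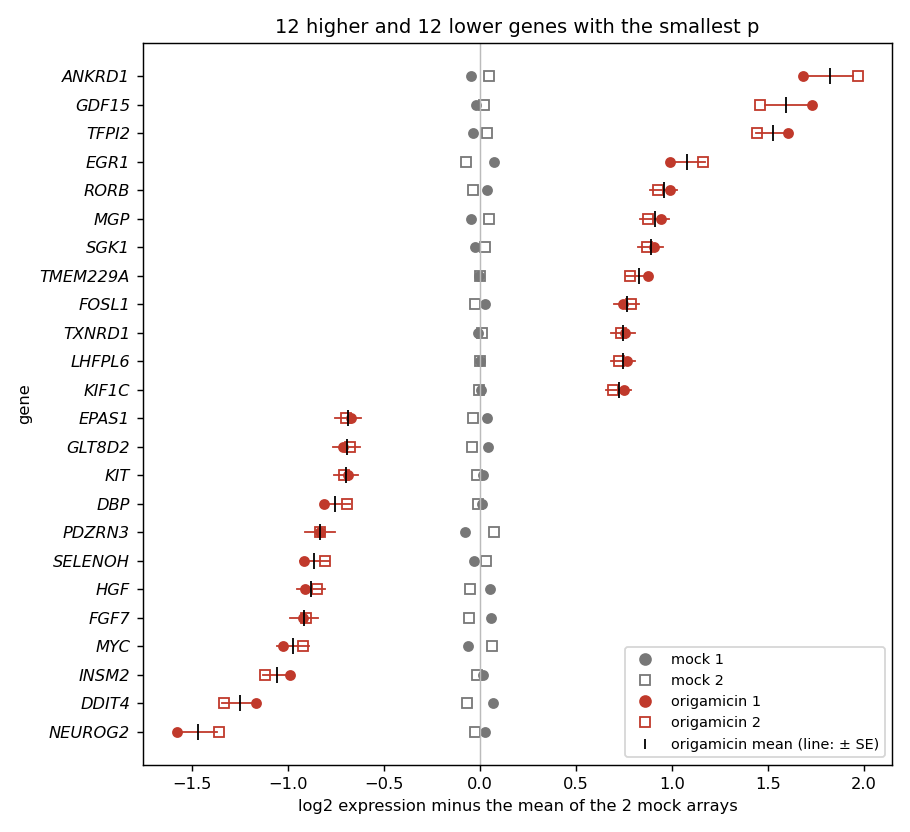
Log2 expression of the 24 genes with the smallest p, 12 higher and 12 lower in origamicin-treated cells, on each of the 4 arrays (grey, mock; red, origamicin; filled circles, replicate 1; open squares, replicate 2), relative to the mean of the 2 mock arrays. The black tick is the mean of the origamicin arrays and the red line its difference from mock ± the moderated SE; the changes run from -1.47 (NEUROG2) to 1.83 (ANKRD1), and for each gene shown the groups are separate.

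The second question was which gene groups shifted together. Of the 28 lists tested, 10 passed camera with the preset correlation: 6 shifted upward and 4 downward relative to other genes. With a correlation estimated from these 4 arrays none passed, the smallest adjusted p being 0.23. In data simulated at this size that setting called a true shift of 0.3 in 0 of 20 draws. The estimate was below the preset 0.01 for some of the 10 lists (-0.033 for p53 targets, -0.035 for glycolysis). For others it was above (0.16 for ER chaperones, 0.21 for ER-associated degradation). A higher correlation therefore does not account for every lost call. With an estimated correlation, camera takes its p from the 2 residual degrees of freedom of these arrays. Even p53 targets then had an unadjusted camera p of 0.022. No member of any list passed over all genes. Counts of passing members are therefore given adjusted over the list alone and for the fit with an intensity trend. Many members had no named probe set, so each list result covers only the genes tested. Those named were 14 of 32 for NRF2, 14 of 26 for p53 and 19 of 32 for PERK-ATF4 targets. For ER-associated degradation they were 12 of 22, for heat shock (HSF1) targets 10 of 22 and for glycolysis 9 of 20.

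Targets of p53 and of NRF2 showed the largest upward shifts. The p53 target list had a mean log2 change of 0.41 ± 0.01 (SE of the list's mean between arrays), with 13 of 14 tested genes higher (camera adjusted p = 1.9e-08; adjusted p = 0.23 with an estimated correlation). Over the list alone 8 genes rose and none fell, and 7 rose with an intensity trend. GDF15, SPATA18 (0.65 ± 0.08), the pro-apoptotic BCL2 family member BAX (0.46 ± 0.06) and the nuclease AEN (0.40 ± 0.06) led it. GDF15 responds to several stress pathways, and without it the mean was 0.32 and the list's camera adjusted p 4.3e-07. The NRF2 target list, genes of the oxidative stress response, had a mean of 0.32 ± 0.02, with 13 of 14 higher (camera adjusted p = 1.3e-06; adjusted p = 0.23 with an estimated correlation). Over the list alone 10 rose and 1 fell, and 8 rose with an intensity trend. Its leading members were TXNRD1, the autophagy receptor SQSTM1 (0.70 ± 0.07), sulfiredoxin SRXN1 (0.60 ± 0.06) and transketolase TKT (0.45 ± 0.08). The autophagy and lysosome list, which shares SQSTM1 with it, shifted upward by less (mean 0.15 ± 0.02, 20 of 24 higher, camera adjusted p = 7.4e-04; adjusted p = 0.23 with an estimated correlation). SQSTM1 was its only gene to pass over the list alone. SQSTM1, TFE3 (0.47 ± 0.09), a transcription factor of lysosomal genes, and the lysosomal channel MCOLN1 (0.25 ± 0.06) passed with an intensity trend. The related factor TFEB stood at 0.45 ± 0.13.

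Since the compound is described as a PDI inhibitor, the ER lists were of particular interest. The ER chaperone list of the ATF6 and XBP1 arms of the unfolded protein response shifted upward, with all 14 tested genes higher and a mean of 0.21 ± 0.02 (camera adjusted p = 4.0e-06; adjusted p = 0.33 with an estimated correlation). Over the list alone 4 rose: the lectin chaperones CALR (0.34 ± 0.07) and CANX (0.26 ± 0.06), the transcription factor XBP1 (0.33 ± 0.07) and the secreted ER protein MANF (0.31 ± 0.08). CALR, CANX and XBP1 also passed with an intensity trend. The ER-associated degradation list shifted upward by 0.10 ± 0.02, with 9 of 12 higher (camera adjusted p = 0.028; adjusted p = 0.50 with an estimated correlation). None of its genes passed over the list alone, FAF2 (0.22 ± 0.06), AUP1 (0.22 ± 0.07), DERL2 (0.14 ± 0.07) and NPLOC4 (0.15 ± 0.07) coming closest, and the call was lost without either mock array or without origamicin replicate 2 (adjusted p = 0.099, 0.059 and 0.24). It was also lost with fry (adjusted p = 0.091) and without any 1 of 5 members, FAF2, AUP1, DERL2, NPLOC4 or SEL1L (adjusted p up to 0.072). The secretory transport list did not pass camera (mean 0.07 ± 0.01, adjusted p = 0.072) but passed with fry, quantile normalization and an intensity trend (adjusted p = 0.032, 0.036 and 0.038; adjusted p = 0.38 with an estimated correlation), and SEC61A1 (0.23 ± 0.06) and SAR1B (0.24 ± 0.07) had its smallest p.

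The PERK-ATF4 target list did not pass (mean -0.0034 ± 0.043, 8 of 19 higher, camera adjusted p = 0.33). Its members went both ways: over the list alone 2 rose and 4 fell, with GDF15 and DDIT4 at the extremes. ATF4, the transcription factor of this arm, stood at -0.07 ± 0.06 (95% interval -0.24 to 0.10), and DDIT3, which encodes the pro-apoptotic factor CHOP, stood at 0.77 ± 0.26 (adjusted p = 0.27 with limma), on values from 4.26 to 4.64 in mock and 4.90 to 5.55 in treated cells. The list of PDI family members and ER oxidoreductases did not pass either (mean -0.04 ± 0.03, 4 of 15 higher, camera adjusted p = 0.41). Its smallest p were those of the sulfhydryl oxidase QSOX1 (0.29 ± 0.06) and of ERO1B (0.19 ± 0.07), and QSOX1 passed with an intensity trend. P4HB, PDIA3, PDIA4, PDIA6 and the chaperone HSPA5 were not analysed here. Heat shock (HSF1) targets also did not pass (mean 0.02 ± 0.04, 7 of 10 higher, camera adjusted p = 0.67), with BAG3 at 0.20 ± 0.07 and HSPD1 at -0.13 ± 0.07. Cytosolic aminoacyl-tRNA synthetases did not pass camera (mean -0.05 ± 0.0046, 11 of 17 lower, adjusted p = 0.26) but passed fry (adjusted p = 0.029; adjusted p = 0.50 with an estimated correlation), with VARS1 at -0.21 ± 0.07 and KARS1 at -0.18 ± 0.06.

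**Figure D2:**
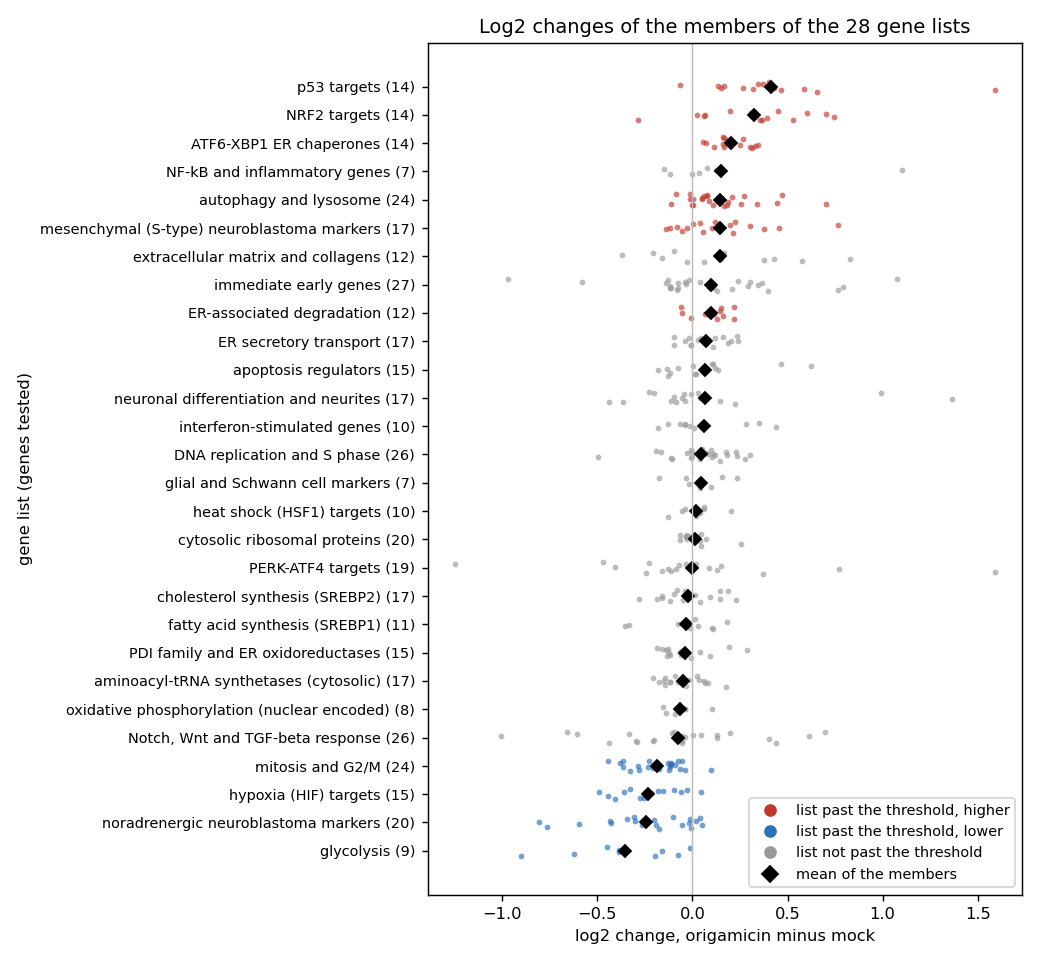
Log2 change (origamicin minus mock, 2 arrays per group) of each tested member of the 28 gene lists, 1 point per gene, with black diamonds for list means and the number of genes tested in parentheses. Red and blue lists passed camera with the preset correlation upward (6) and downward (4), and 0 lists passed with an estimated correlation. List means run from -0.35 (glycolysis) to 0.41 (p53 targets).

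Genes of glycolysis and of the hypoxia response were lower together. All 9 tested glycolysis genes were lower, with a mean of -0.35 ± 0.03 (camera adjusted p = 3.1e-05; adjusted p = 0.23 with an estimated correlation). Over the list alone 4 fell: hexokinase HK2 (-0.90 ± 0.09), PGAM1 (-0.62 ± 0.07), lactate dehydrogenase LDHA (-0.45 ± 0.07) and PGK1 (-0.39 ± 0.07), and these 4 and GPI passed with an intensity trend. Among hypoxia (HIF) targets, 14 of 15 were lower, with a mean of -0.23 ± 0.0027 (camera adjusted p = 1.9e-05, and 0.23 with an estimated correlation). The small SE of this mean rests on list means that lay close together on the 2 arrays of each group (SD 0.00097 in mock, 0.0037 in origamicin). The mitophagy receptor BNIP3 (-0.49 ± 0.06), lysyl oxidase LOX (-0.45 ± 0.08), STC2 (-0.41 ± 0.08) and the angiogenic factor VEGFA (-0.36 ± 0.07) fell over the list alone. BNIP3, LOX and VEGFA passed with an intensity trend. Nuclear-encoded oxidative phosphorylation genes did not pass (mean -0.06 ± 0.02, 7 of 8 lower, camera adjusted p = 0.32, fry adjusted p = 0.080), with UQCRC2 at -0.15 ± 0.06 and COX7B at -0.09 ± 0.07, although only 8 of 34 were named on the array.

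The mitosis and G2/M list fell by 0.18 on average (SE 0.01), with 23 of 24 genes lower (camera adjusted p = 3.6e-06; adjusted p = 0.23 with an estimated correlation). Over the list alone 5 fell and none rose, and 6 fell with an intensity trend. The leading members were the mitotic kinesin KIF20A (-0.37 ± 0.07), the kinase PLK1 (-0.38 ± 0.07) and the cyclins CCNB2 (-0.36 ± 0.07) and CCNB1 (-0.33 ± 0.06). The DNA replication and S phase list did not pass (mean 0.04 ± 0.01, 16 of 26 higher, camera adjusted p = 0.11), with the helicase subunit MCM7 at -0.50 ± 0.06, which fell over the list alone, and E2F1 at 0.23 ± 0.06. With an intensity trend this list did pass, upward (camera adjusted p = 0.038). Without the trend it had an adjusted p = 0.38 with an estimated correlation.

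Markers of 3 cell types were examined. The noradrenergic neuroblastoma list had a mean of -0.24 ± 0.01, with 17 of 20 lower (camera adjusted p = 3.6e-06; adjusted p = 0.23 with an estimated correlation). Over the list alone 9 fell, and 10 fell with an intensity trend. The granule proteins CHGA (-0.80 ± 0.09) and CHGB (-0.76 ± 0.08), the catecholamine synthesis enzyme DDC (-0.59 ± 0.06) and MAB21L1 (-0.43 ± 0.06) led it. Markers of mesenchymal (S-type) neuroblastoma cells, the other cell type that SH-SY5Y cultures can hold, shifted upward by 0.14 ± 0.03, with 12 of 17 higher (camera adjusted p = 0.018; adjusted p = 0.38 with an estimated correlation). FOSL1, the intermediate filament gene VIM (0.45 ± 0.07) and fibronectin FN1 (0.37 ± 0.08) rose over the list alone, and these and SNAI2 (0.30 ± 0.08) passed with an intensity trend. The mesenchymal call was lost without mock replicate 2 or origamicin replicate 2 (adjusted p = 0.15 and 0.088). It was also lost with fry (adjusted p = 0.091) and without FOSL1 or VIM (adjusted p up to 0.072). The other 2 named probe sets of VIM changed by 0.31 and 0.53. Glial and Schwann cell markers did not pass (mean 0.04 ± 0.03, camera adjusted p = 0.66), with FOXD3 at -0.18 ± 0.12 and GFAP at 0.23 ± 0.16.

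The remaining lists did not pass camera, and several held single genes with large changes. The neuropeptide NPY (1.37 ± 0.16) and the secreted VGF (0.99 ± 0.14) rose over the neuronal differentiation list alone, while MAPT (-0.37 ± 0.07) and GAL (-0.44 ± 0.09), chosen after their values were seen, fell. In this list 11 of 17 genes were lower (camera adjusted p = 0.67, downward, with a median of -0.04 and a mean of 0.07). Among immediate early genes, MYC fell and FOSL1 rose over the list alone, in which 7 rose and 2 fell (camera adjusted p = 0.12, and 0.049 with the 60th percentile filter; adjusted p = 0.38 with an estimated correlation). Among Notch, Wnt and TGF-β response genes, the Wnt antagonist DKK1 (0.70 ± 0.07) and the receptor LGR5 (0.61 ± 0.08) rose over the list alone, in which 4 rose and 4 fell. The Notch ligand JAG1, chosen after its values were seen, fell over the list alone with the largest change of the list (-1.01 ± 0.15), and 17 of 26 members were lower (camera adjusted p = 0.33, downward). The anti-apoptotic BCL2 (0.63 ± 0.07) and BAX were the 2 apoptosis regulators that rose over the list alone (adjusted p = 0.32). The chemokine CCL2 (1.10 ± 0.20) rose over the NF-κB list alone, ICAM1 stood at -0.15 ± 0.08, and the list did not pass (adjusted p = 0.41). The matrix genes NID1 (0.43 ± 0.06) and THBS1 (0.83 ± 0.14) rose over the extracellular matrix list alone (4 rose, camera adjusted p = 0.11). That list passed with fry, the 60th percentile filter and an intensity trend (adjusted p = 0.033, 0.048 and 0.042; adjusted p = 0.38 with an estimated correlation).

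No gene passed over the list alone in 4 further lists. Interferon-stimulated genes had a camera adjusted p of 0.44, with a median of -0.03 against a mean of 0.06 ± 0.06 (SE of the list's mean between arrays). IRF9 (0.35 ± 0.08) and RIGI (0.44 ± 0.11) had the smallest p. Cholesterol synthesis genes had an adjusted p of 0.66, with MSMO1 at -0.28 ± 0.07 and PMVK at 0.23 ± 0.07. Fatty acid synthesis genes had an adjusted p of 0.79, with the desaturase SCD at -0.33 ± 0.07 (-0.63 on its other, dimmer named probe set) and SREBF1 at -0.36 ± 0.13. Cytosolic ribosomal protein genes had an adjusted p of 0.67, with RPL11 at 0.26 ± 0.07 and RPL14 at -0.07 ± 0.06. MSMO1, SCD and RPL11 passed with an intensity trend. Metallothionein and aryl hydrocarbon receptor target lists had too few tested genes for a test, 4 and 1.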

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

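The strongest single change lay in the data left out of the comparisons. Probe set 16827679, which the annotation used here pairs with no gene, was 2.92 ± 0.08 (SE) higher on the log2 scale in treated cells, from 7.03 and 7.05 on the mock arrays to 10.0 and 9.92 on the origamicin arrays. In a limma fit over all 32170 probe sets above the same level its adjusted p was 0.098, and no probe set passed 0.05 in that fit. Of the 19371 unnamed ones, 2024 had an unadjusted p under 0.05 there. This is a smaller share than the 1950 of 11883 named genes in the main fit, though the fits differ. By size the share was larger. A log2 change of at least 1 was seen for 133 of the 19371 unnamed probe sets and for 15 of the 11883 genes. Probe set 16827679 drew attention as a signal above the mock level in data outside the main measurement. No explanation was tested.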

How the results depend on the processing

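The count of 0 genes past the threshold held under the replicate block, no filter, equal array medians, quantile normalization and mean probe sets. It also held under robust eBayes, all probe sets and cyclic loess (chosen after seeing the data). A minimum log2 change of 1 only takes genes away, so it could not change a count of 0. Under the replicate block the smallest adjusted p was 0.30. The 53 genes under 0.1 became 0 with the block, with no filter, with robust eBayes and without each array (smallest adjusted p from 0.10 to 0.46 over these fits), 52 to 79 with mean probe sets, equal medians and quantile normalization, 497 with the 60th percentile filter and 987 with an intensity trend. The genes past the threshold were 92 (genes higher, 51; genes lower, 41) with the 60th percentile filter and 511 (254 higher, 257 lower) with an intensity trend, and 53 (32 higher, 21 lower) at an adjusted p under 0.1. The median residual SD fell from 0.15 in the dimmest to 0.05 in the brightest quintile of genes, which a single prior variance does not follow. All 93 genes named by the rule kept their sign in each fit, or all 85 that were held at the 60th percentile. Signs were not counted under cyclic loess or all probe sets. The block, the filters, the trend and robust eBayes leave a gene's log2 change as it was. Leaving out 1 array cannot turn the sign of a gene whose groups do not overlap. In those fits the kept sign is no support for a change. All 10 lists past the threshold passed in the same direction under the block, both filters, both normalizations, cyclic loess, mean probe sets, an intensity trend and robust eBayes. Leaving out 1 array kept 8 to 10 of them, and fry 8 of 10, without the mesenchymal and ER-associated degradation lists. With an estimated correlation 0 lists passed. Without each member in turn, 8 of the 10 lists passed throughout, while the mesenchymal list was lost without 2 of its members and ER-associated degradation without 5 (adjusted p up to 0.072). Over the fits without 1 array, the mean change ran from -0.054 to 0.012 for cholesterol synthesis, from -0.065 to -0.0059 for fatty acid synthesis, from -0.0059 to 0.047 for heat shock and from 0.038 to 0.092 for neuronal differentiation, lists that did not pass and whose direction in camera turned in at least 1 of these fits; the cause was not tested. The mean of PERK-ATF4 targets ran from -0.043 to 0.036 and that of the PDI family from -0.063 to -0.012, neither passing in any of these fits. With 1 array left in a group, that array is assumed to vary like the other group. The differences between replicates 1 and 2 correlated between the groups at r = -0.023 across genes, which are not independent, and the arrays share only a number.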

Other observations

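The 6 lists used here were drawn up after the results above were seen, and the tests of the noradrenergic share and of energy metabolism were chosen after their results were seen. Genes of ERK pathway output, asked about because EGR1, FOSL1 and SPRY4 (0.79 ± 0.08 SE) were higher, shifted upward also without the genes seen before, with 8 of 10 higher and a mean log2 change of 0.18 (camera adjusted p = 0.0127 over the 6 lists; adjusted p = 0.44 with an estimated correlation). The ETS factors ETV4 (0.43 ± 0.07) and ETV5 (0.42 ± 0.08), the growth factor HBEGF (0.30 ± 0.06) and the cytokine LIF (0.41 ± 0.10) were its higher members with the smallest p, while ETV1 stood at -0.27 ± 0.09. With the genes seen before, 15 of 18 were higher, and among those seen before DUSP6 stood at -0.14 ± 0.07. Higher ERK output is a hypothesis that this list is consistent with, and no ERK activity was measured.

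The same question for 4 other genes or gene pairs gave no call. YAP-TEAD targets without ANKRD1 and the other genes seen before had 9 of 11 higher (mean 0.08, camera adjusted p = 0.158). Proneural factors without NEUROG2, INSM2 and the others seen before had 14 of 19 lower (mean -0.07, camera adjusted p = 0.158). Selenoproteins other than SELENOH, TXNRD1 and others seen before had 9 of 13 lower (mean -0.05, camera adjusted p = 0.488), and secretory granule genes without CHGA, CHGB and others seen before had 7 of 13 lower (mean -0.05, camera adjusted p = 0.488). These lists leave open whether the single genes stand for their pathways.

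Lists shifted between the groups although no single gene passed. Variation between arrays shared by the genes of a list would also shift lists within groups, but 0 of the 28 lists passed in either of the other 2 splits of the 4 arrays, against 10 in the real one, all at the preset correlation. With an estimated correlation 0 lists passed in the real split, and with 3 splits no share under 0.05 can be had. The other splits kept the treatment in the model, which left fewer degrees of freedom, so the counts are not on equal terms. An intensity-dependent difference between arrays is argued against by cyclic loess, after which 10 of the 10 lists passed in the same direction. An effect of the compound stays open as a hypothesis, as does any handling difference between the groups.

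Of the noradrenergic markers 17 of 20 were lower (adjusted p = 0.23 with an estimated correlation), and 12 of 17 mesenchymal markers were higher, a call lost with an estimated correlation (adjusted p = 0.38), with fry, without either of 2 arrays and without FOSL1 or VIM. A smaller share of noradrenergic cells would lower its markers by a common amount only if the other cells lacked all of them. The changes of the noradrenergic markers ran from -0.80 (CHGA) to 0.05 (KLF7). Their spread per degree of freedom was 12.01, where the 95th percentile of 10000 simulated common shifts was 0.82. This argues against a single common fall of all the markers. Their level in other cells was not measured, so the test cannot decide on a changed share. A change in cell share, alone or beside regulation of single genes, stays open.

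Genes of the hypoxia list and of glycolysis were lower together, though both calls were lost with an estimated correlation (camera adjusted p = 0.23 for each). The mean of oxidative phosphorylation genes lay 0.291 ± 0.098 (SE across genes, taken as independent) above that of glycolysis genes. This argues against a loss of RNA of the same size for all energy metabolism, in a comparison chosen after both means were seen. With 7 of 8 oxidative phosphorylation genes lower, and only 8 of 34 named on the array, a smaller loss there stays open. Lower MYC, which was itself lower, is a candidate explanation that stays open. Of 19 MYC-driven nucleolar and ribosome biogenesis genes 16 were lower, with a mean of -0.06 and a camera adjusted p of 0.158. The member with the smallest p, ODC1, was higher (0.28 ± 0.06 SE). Lower HIF activity, with EPAS1 lower, was not tested.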
